A study of Mus musculus with 12 samples.

How the data were processed

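Single-cell RNA was measured in sorted interfollicular keratinocytes of C57BL/6 mice, in 12 libraries of 6 groups with 2 replicates each, made with the Chromium Single Cell 3′ kit v3 per the labels. The deposited values are counts of UMIs per gene and barcode, made with Cell Ranger 3.1.0, with Seurat 3.1 and mm10 named in the submitters' processing notes. The annotation and whether the counting used strand are not given in the sources used here. The matrices held 31053 genes, among them no reporter construct. Gene coordinates come from GENCODE vM21 on GRCm38, which is the mm10 assembly, and 99.62% of the features matched by gene identifier. Groups and replicate numbers were taken from the sample titles, ages and the doxycycline times from the other labels.

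A barcode was kept with at least 1000 UMIs, at least 500 detected genes and at most 15% of UMIs from mitochondrially encoded genes, which removed 68363 of 105446 barcodes, mainly through the mitochondrial limit. The kept cells of all libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 (log of counts scaled to a common total, 3000 variable genes chosen within library, 30 principal components, 15 nearest neighbours, Leiden resolution 1, no batch integration). Clusters were called "X-like" from markers listed in advance, and clusters led by endothelial or immune markers were left out of the sums. Basal-like clusters had no basal marker among their 10 leading genes and were called so from 3 to 6 of 8 basal markers at 1.5 times or more of their mean level in the suprabasal-like clusters, a comparison chosen after seeing the data. They include clusters 3 and 12, almost wholly from tail, where the hair follicle markers Postn and Sostdc1 were among the 10 leading genes, so the class in tail holds cells with leading markers of another class. They also include cluster 7, from tail, whose first leading gene was Dcn, a gene of the fibroblast list, at 65.6 CPM. Other fibroblast markers were near absent there, with Col3a1 at 0 and Col1a1 at 0.079 CPM. Krt14 averaged 33971 CPM and Krt5 10835 CPM in it. The suprabasal-like cluster of tail, 2276 cells, had the scale keratins Krt36 and Krt84 before Krt2, Krt1 and Krt10 among its leading genes. Clusters of low UMI counts, clusters with replication genes among their leading genes and a group of 21 cells led by the hair keratins Krt71 and Krt25 stayed unnamed. The second kind, called replication-led here, includes cluster 23, of 233 back cells, where the hair follicle markers Krt17 and Krt24 came first. Sums without hair follicle-like clusters kept this cluster. Scrublet marked 71 of 37083 cells, under 0.5%, so this doublet caller has not worked here, doublets were kept, and the highest scores were left out in an alternative. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.

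Counts were summed per library over the keratinocyte clusters, so that libraries and not cells were the replicates. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM, filterByExpr, robust dispersion) in 1 fit of 12 libraries with 6 group means and 6 residual degrees of freedom, with Benjamini-Hochberg adjustment over 13583 genes. Levels are CPM, UMI counts scaled to the effective library size, and log2 differences are given with their SE. DESeq2 1.42.0 was the other tool. Gene lists were fixed before the data were examined, 46 in all, of which 43 with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Medians of lists are from the fit without the replicate block described next, also beside a camera test with it, except where a median is given as with the block. Shares of cells were compared with exact permutation tests that permuted labels within a skin.

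Replicate numbers come from the sample titles. Libraries with the same number deviated together within a skin, with correlations of their deviations from the group means of 0.57 to 0.70 in all 6 pairs of groups, whereas across skins the correlations lay between -0.19 and 0.02. The number was taken as a pairing within each skin when the clusters were seen to split by replicate, before any fit, and these correlations were first read together with the calls of both fits. With 2 replicates the deviations of a group are mirror images, so each pair of groups gives 1 correlation. Between fractions, results with the replicate number as a block within each skin, 4 residual degrees of freedom, are given beside those without it. For tail against back another model was used, with 1 replicate effect common to both skins and 5 residual degrees of freedom, although the numbers did not pair libraries across skins. Replicates of a group differed beyond sampling noise, with a chi-square per degree of freedom of 34.3 to 88.3, so no pair was counted as 1 sample. That does not show that they came from separate animals.

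Named genes followed a rule set before the data were examined. It took the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM, no overlap between the libraries compared and no predicted gene symbol, 5 and 5 for the mean and for the difference of both skins, up to 4 members with the smallest adjusted p of each list described, and 16 genes always named. Since the fit without the block called 0 genes between LRC and nonLRC, the rule was applied there to the fit with the block, a choice made after the counts of both fits were seen that departs from a plain reading of the rule. Only 4 rising genes met it for the mean of both skins. The value of 1 list member is not reported here. For genes at 0 counts in a group the fold is a lower bound against 3 counts per library, and with 1 to 3 counts it is a ratio of CPM with its counting interval, which covers counting error only.

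The fits were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. For LRC against nonLRC the means were taken per skin and replicate number, and the spread from the model with the block. A replicate difference was thus planted, so better recovery with the block follows from the setting and does not show that the block is right. For LRC against nonLRC in back, 24.2% of genes changed by log2 1 were recovered without the block and 71.7% with it, and 66.7% and 83.8% of those changed by log2 2, over 13452 genes. In tail these were 26.0% and 78.0%, and 56.0% and 87.0%, over 13443 genes. Of the genes called with the block 8.88% in back and 8.84% in tail had not been changed, above the 5% aimed at.

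Alternatives set before the data were examined were another normalization (RLE), DESeq2, no filter on low counts, other sets of cells (all barcodes, basal-like alone, without cycling-like clusters, a stricter cell filter, without Scrublet doublets, equal cells per library), the libraries of 1 skin alone, the replicate block and leaving out each library. Alternatives chosen after seeing the data left out the hair follicle-like clusters, 4 clusters of low UMI counts or extreme mitochondrial share, the replication-led clusters or the highest doublet scores, set a mitochondrial limit of 10% or none, summed the fractions of each skin and replicate number for tail against back, or joined another setting to the block.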

Results

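The data were single-cell RNA counts from the interfollicular epidermis of mice, the skin surface epithelium between hair follicles. The mice carried a histone H2B fused to green fluorescent protein under a doxycycline-repressible keratin 5 driver, so that cells which divided while doxycycline was fed diluted the label and cells which divided rarely kept it. Basal cells positive for α6 integrin and Sca1 had been sorted by label into a retaining fraction (LRC), an intermediate fraction (midLRC) and a fraction without the label (nonLRC). Each fraction came from back skin at postnatal day 47 and from tail skin at postnatal day 51, with 2 replicate libraries per fraction and skin, 12 libraries in 6 groups. Doxycycline chow had been given for 2 or 3 weeks, and the labels do not say which library had which. The labels also do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Those with the replicate block measure only the spread left after the difference between replicate numbers of a skin is taken out.

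The 12 libraries held 105446 barcodes and between 24055463 and 46878426 UMIs each, and 37083 barcodes passed the cell filter. The number kept ran from 722 in tail nonLRC replicate 1, which was 7.15% of its barcodes, to 7120 in tail midLRC replicate 2. Basal-like clusters, named from basal markers above their level in suprabasal-like clusters, held 57.7% of the kept cells, and cycling-like clusters held 14.6% and suprabasal-like clusters 12.1%. The first share includes tail clusters of 2617 and 1350 cells with the hair follicle markers Postn and Sostdc1 among their leading genes. It also includes cluster 7, of 2040 tail cells, whose first leading gene was Dcn, a gene of the fibroblast list. Like the other basal-like clusters it had no basal marker among its 10 leading genes. The fibroblast marker Col1a1 averaged 0.079 CPM in it and Krt14 33971 CPM. Upper hair follicle-like cells made up 2.27% and hair follicle bulge-like cells 0.531%, and 12.6% were in clusters without a name. Only 29 cells were endothelial-like and 32 immune-like. The sums tested held 716 to 7118 cells and 5468939 to 38469293 UMIs per library. In a principal component analysis of these sums the first component, with 69.9% of the variance, separated back from tail.

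The first question was how label-retaining basal cells differ from cells that lost the label in back skin. With the replicate number as a block, the genes that rose most in LRC, among those averaging at least 10 CPM whose libraries did not overlap, were Calml3, a calmodulin-like gene of differentiating epithelia, and Col4a1, a collagen chain of the basement membrane. Calml3 averaged 6.46 CPM in nonLRC and was 3.35 times higher in LRC, a log2 difference of 1.74 ± 0.19 (SE, n = 2 against 2, edgeR adjusted p = 0.00206), and Col4a1 rose by 1.27 ± 0.13 (adjusted p = 2e-04). The chitinase gene Chit1 rose from 182 to 429 CPM, and Pyy, which encodes peptide YY, from 126 ± 31.6 to 275 ± 90.5 CPM (SD, n = 2), with an edgeR adjusted p of 9.66e-06. Kcnj16, Guca2a, Them5, H2-M2, Nat8l and Cyp3a13 rose by 0.95 to 1.08 on the log2 scale. Those that fell most, within the same limits, were the neighbours Tmem176a and Tmem176b, at log2 -2.12 ± 0.16 and -2.03 ± 0.20, and Tmem176a stood at 5.17 CPM in LRC (edgeR adjusted p = 1.68e-05). Capn2, a calpain protease, fell by 1.49, Lgals9 by 1.37, the sodium pump subunit gene Atp1b1 by 1.25 and Timp3, an inhibitor of metalloproteinases, by 1.22. Dlc1, Thy1, Casp1 and Ptn fell by 1.07 to 1.17. Cluster makeup moved with some of these genes. Dlc1 was among the leading genes of cluster 9, which held 66 of 2322 cells in LRC and 507 of 4763 in nonLRC of replicate 1, and 18 of 1919 and 512 of 2223 in replicate 2. Pyy and H2-M2 were among those of cluster 1, with 1368 of 1919 and 1050 of 2223 cells in LRC and nonLRC of replicate 2, and 21 of 2322 and 38 of 4763 in replicate 1. Each of these 20 genes moved the same way in both replicate pairs, which their choice for libraries without overlap builds in. Tmem176a and Tmem176b overlap on opposite strands, as do Col4a1 and Col4a2, and whether the counting used strand is not given in the sources used here.

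Genes of early epidermal differentiation were higher in back LRC as a group, with 5 of 19 measured members rising and none falling, and 9 when adjusted over the list alone (camera with the block, adjusted p = 1.34e-07, and adjusted p = 0.378 with an estimated correlation). Besides Calml3 these were led by Krt77 (log2 0.42), Calm4 (0.57) and Krt10 (0.45), a keratin of suprabasal cells. Hair follicle cells moved with them. Calml3 was among the leading genes of the bulge-like cluster. Upper hair follicle-like cells, with the highest Krt10 and Krt77 of the back clusters, were 1.24% ± 0.533 of back LRC and 0.487% ± 0.0531 of back nonLRC (SD, n = 2). Without the hair follicle-like clusters Calml3 stood at 0.463 and no longer passed. The list then passed at the preset correlation (camera with the block, adjusted p = 0.00725, and adjusted p = 0.481 with an estimated correlation). Of the genes named in advance, Krt14, a keratin of basal cells, fell by 0.43 (edgeR adjusted p = 0.0335) and Krt15 rose by 0.40 (adjusted p = 0.0488). Krt5, Itga6, Col17a1, Ly6a (the Sca1 gene), Mki67, Top2a, Dlx1 and Slc1a3 did not pass the test. Hypoxia response genes rose in 5 of 16 members, 9 adjusted over the list alone, with Ndrg1 at 0.61, Bnip3 at 0.54 and Vegfa at 0.67 (camera with the block, adjusted p = 5.38e-07, and adjusted p = 0.252 with an estimated correlation). Immediate early and dissociation genes, often raised by tissue handling, rose in 3 of 27, 4 adjusted over the list alone, Dnajb1 by 0.44, Hspa1a by 0.39 and Egr3 by 0.52 (camera with the block, adjusted p = 0.00107, and adjusted p = 0.31 with an estimated correlation). Circadian clock genes rose in 4 of 17, 9 adjusted over the list alone, among them Hlf (0.52), Ciart (0.96) and Dbp (0.44), with an adjusted p of 2.85e-06 by camera with the block, and adjusted p = 0.252 with an estimated correlation. Genes of nuclear oxidative phosphorylation were lower as a group, at a median log2 difference of -0.14 over 86 members (camera with the block, adjusted p = 3.46e-09, and adjusted p = 0.458 with an estimated correlation), although only Cox6b2 and Ndufa4 fell singly. Cluster 22, with a median mitochondrial share of 13.1%, held 139 of 1919 cells in LRC and 43 of 2223 in nonLRC of replicate 2. In replicate 1 it held 4 of 2322 and 5 of 4763. The median mitochondrial share of the libraries went both ways, at 6.01% in LRC and 5.24% in nonLRC of replicate 1, and 3.99% and 5.58% in replicate 2.

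Genes of the hair follicle bulge were also higher in back LRC, with a median log2 difference over 9 measured members of 1.54 with the block and 1.52 without it. Among them 2 rose, Tbx1 by 3.05 and Cd34 by 4.63, and 7 when adjusted over the list alone (camera with the block, adjusted p = 2.49e-05, and adjusted p = 0.31 with an estimated correlation). Cd34 averaged 3.34 CPM in LRC and 0.129 in nonLRC, and the members Sox9 and Postn stood at -0.72 and -0.77. Bulge-like cells were 1.60% ± 0.786 of kept cells in back LRC (SD, n = 2) and 0.151% ± 0.0233 in back nonLRC. In tail they were 0.144% ± 0.0101 in LRC and 0.929% ± 0.530 in nonLRC. Sebaceous gland genes rose in 3 of 10 members, Elovl3, Cidea and Far2, and 5 adjusted over the list alone (camera with the block, adjusted p = 0.00233, and adjusted p = 0.31 with an estimated correlation), each at under 3 CPM. The fibroblast gene Dcn rose by 2.15 and Sparc fell by 0.47, and that list of 6 did not pass. Xist, expressed from the inactive X chromosome, stood at 138 UMIs in back LRC replicate 1, in 13 of 2322 cells, and at 33 UMIs in back midLRC replicate 1, in 4 of 3573 cells, against 1 to 4 UMIs in the other 4 back libraries, while the Y-linked Ddx3y was near 77.2 CPM on average across back libraries.

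Counts of changed genes in back depended on the pairing of the libraries. With 6 group means alone edgeR called 0 of 13583 genes at an adjusted p under 0.05, with 505 at an unadjusted p under 0.05 and 56 called by DESeq2, whereas the replicate block gave 460, of which 241 rose and 219 fell. The blocked count was 763 without back nonLRC replicate 1, 299 without tail midLRC replicate 1, 295 without tail nonLRC replicate 1 and 288 without tail nonLRC replicate 2. It was 58 from the 6 back libraries alone, 246 with the stricter cell filter, 276 with equal cells, 1019 with no filter on low counts and 294 by DESeq2.

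**Figure D1:**
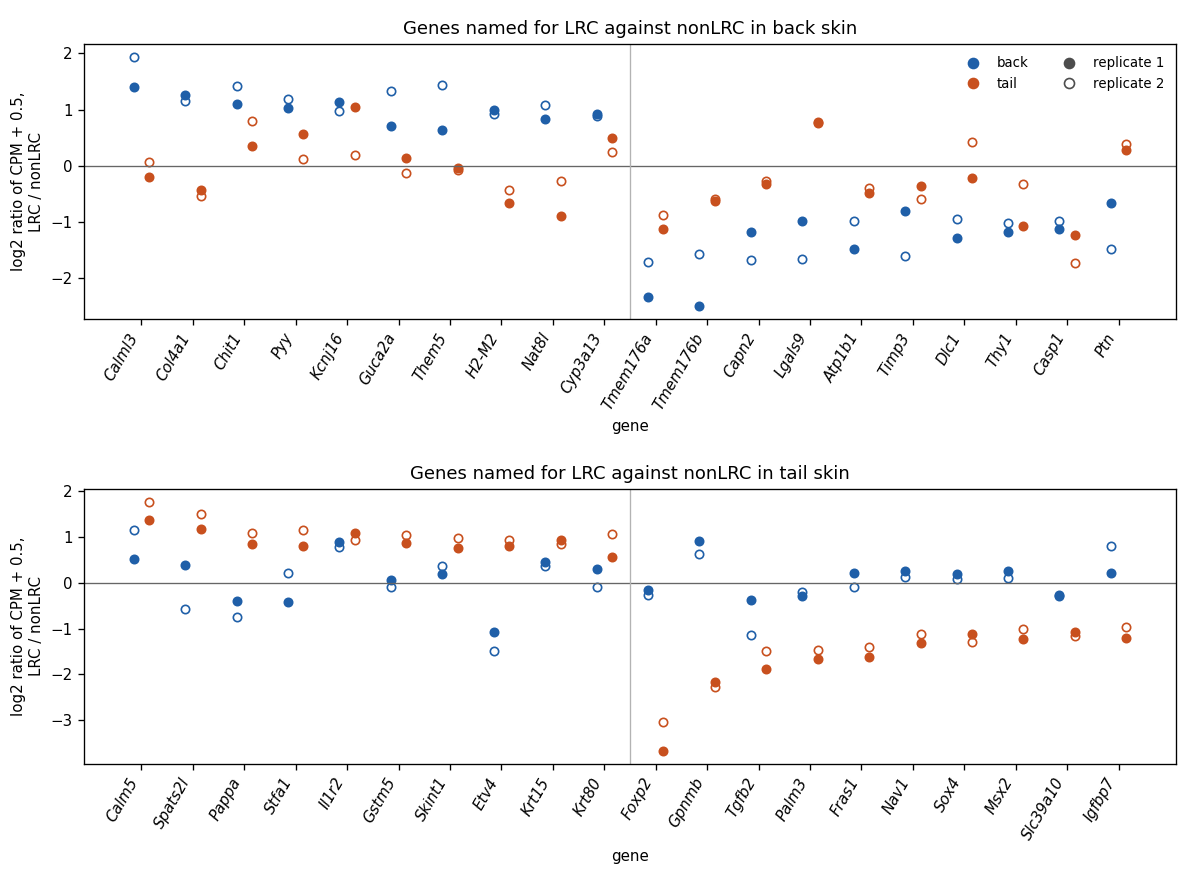
Log2 ratio of CPM + 0.5 in LRC over nonLRC for the genes named by size of change, one point per replicate pair and skin, replicate 1 filled and replicate 2 open. In back, Pyy and Calml3 lie above 0 and Tmem176a and Tmem176b below 0 in both pairs, and in tail Foxp2 and Gpnmb lie below 0 in both pairs.

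In tail skin the same contrast was marked by genes lower in LRC. Foxp2, a forkhead transcription factor gene on chromosome 6 (14901349 to 15441977, GRCm38), fell from 19.3 ± 2.81 to 1.52 ± 0.889 CPM (SD, n = 2), a log2 difference of -3.62 ± 0.23 (SE, edgeR with the block, adjusted p = 8.08e-06). Gpnmb, a transmembrane glycoprotein gene, fell by 2.29 (edgeR adjusted p = 7.1e-07), from 34.0 and 119 CPM in the nonLRC libraries to 7.16 and 23.9 CPM in the LRC libraries. The growth factor gene Tgfb2 fell by 1.70, Palm3 by 1.62, and Fras1, an extracellular protein gene of the basement membrane, by 1.52. Nav1, Sox4, Msx2, Slc39a10 and Igfbp7 fell by 1.09 to 1.26. Cluster makeup moved with several of these genes. Gpnmb, Palm3, Fras1 and Slc39a10 were among the leading genes of clusters 7 and 4, and Tgfb2 and Msx2 of cluster 7. These clusters held 141 and 166 of 3982 cells in tail LRC replicate 2 and 741 and 1176 of 5829 in nonLRC replicate 2. In replicate 1 they held 0 and 1 of 1466 cells in tail LRC and 1 and 38 of 722 in tail nonLRC. Calm5 rose most among genes within the same limits as in back, from 19.3 to 58.8 CPM, at log2 1.63 ± 0.25 (edgeR adjusted p = 0.0282). Spats2l rose by 1.45, Pappa by 1.03, Stfa1 by 1.01 and the decoy interleukin receptor gene Il1r2 by 1.01, and Gstm5, Skint1, Etv4 and Krt80 by 0.86 to 0.98. Stfa1 has close paralogs and its counts may include theirs. Krt15 rose from 2922 ± 618 to 5460 ± 1400 CPM, at log2 0.89 ± 0.10 (edgeR adjusted p = 0.00055). Cluster makeup moved with rising genes too. Krt15 averaged 10005 CPM in cluster 12 and 1460 in cluster 11. Cluster 12 held 714 of 1466 cells in tail LRC replicate 1 and 235 of 722 in nonLRC replicate 1. Pappa and Gstm5 were among the leading genes of cluster 3, which held 1111 of 3982 cells in LRC replicate 2 and 666 of 5829 in nonLRC replicate 2.

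Hemidesmosome and basement membrane genes fell together in tail LRC, in 11 of 24 members with none rising, and in 17 adjusted over the list alone (median log2 -0.35, camera with the block, adjusted p = 7.17e-11, and adjusted p = 0.385 with an estimated correlation). They included Lamb1 (-0.88), Dst (-0.47) and the β4 integrin gene Itgb4 (-0.42). Cluster 4, which was rarer in LRC of both replicate numbers and had low UMI counts and a median mitochondrial share of 12.2%, had Lamb1, Dst and Col7a1 among its 10 leading genes. Without it and the other low quality clusters the list passed at the preset correlation (camera with the block, adjusted p = 2.61e-08, and adjusted p = 0.356 with an estimated correlation). Of the basal keratinocyte genes 5 of 15 fell and Krt15 rose, with Col17a1 at -0.47, Itga6 at -0.35 and Krt14 at -0.39 (camera with the block, adjusted p = 0.0127, and adjusted p = 0.385 with an estimated correlation). Wnt pathway genes fell in 7 of 31, 9 adjusted over the list alone where 3 others rose, among them Wls (-0.36), Fzd10 (-0.46) and Wnt4 (-0.40) (camera with the block, adjusted p = 0.0121, and adjusted p = 0.385 with an estimated correlation). Cell adhesion and junction genes fell in 3 of 22 and rose in 1, and the gap junction gene Gja1 fell by 0.99 (camera with the block, adjusted p = 0.00743, and adjusted p = 0.385 with an estimated correlation). Melanocyte genes moved the same way, with 2 of 4 falling, Mlana from 0.922 to 0.0805 CPM and Dct from 1.66 to 0.553 CPM, and so did fibroblast genes, with 2 of 6 falling, Dcn from 10.6 to 4.45 CPM and Sparc from 518 to 398 CPM. Their camera tests with the block gave adjusted p = 0.00327 and 0.0121, and adjusted p = 0.385 for both with an estimated correlation. Dcn was the first and Sparc another of the leading genes of cluster 7, which was rarer in LRC of replicate 2. That cluster had Krt14 at 33971 CPM and the fibroblast marker Col1a1 at 0.079 CPM, so these falls need not come from fibroblasts.

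Ribosomal protein genes rose in tail LRC, in 32 of 78 members with none falling, and in 58 adjusted over the list alone (median log2 0.39, camera with the block, adjusted p = 2.72e-32, and adjusted p = 0.385 with an estimated correlation). Rps7 went from 1625 to 2452 CPM and Rpl17 from 2076 to 3012 CPM. Signs of RNA quality moved with them. The median mitochondrial share was 6.26% in LRC and 9.48% in nonLRC of replicate 1, and 5.29% and 5.74% in replicate 2. Cluster 4 held 166 of 3982 and 1176 of 5829 cells in replicate 2, and 1 of 1466 and 38 of 722 in replicate 1. Without the low quality clusters the ribosomal list passed at the preset correlation (camera with the block, adjusted p = 1.87e-29, and adjusted p = 0.435 with an estimated correlation). Genes of the G1/S phase rose in 8 of 28, 13 adjusted over the list alone, with Slbp at 0.64, Mcm4 at 0.49 and Gins2 at 0.61 (camera with the block, adjusted p = 2.24e-11, and adjusted p = 0.385 with an estimated correlation), whereas none of the 30 G2/M genes passed. Nuclear oxidative phosphorylation genes were higher as a group at a median of 0.19 over 86 members, of which Ndufab1 and Cox7a2l rose (camera with the block, adjusted p = 8.48e-10, and adjusted p = 0.385 with an estimated correlation). Immediate early and dissociation genes rose in 4 of 27, 6 adjusted over the list alone where 1 other fell, led by Hspa1a (0.47) and Dusp1 (0.42) (camera with the block, adjusted p = 0.0179, and adjusted p = 0.385 with an estimated correlation). MHC class I genes had a median of 0.33 over 10 members, 1 of them rising and 6 adjusted over the list alone (camera with the block, adjusted p = 0.00875, and adjusted p = 0.385 with an estimated correlation).

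With 6 group means edgeR called 0 genes in tail, with 696 at an unadjusted p under 0.05 and 32 called by DESeq2, and with the replicate block it called 789, of which 324 rose and 465 fell. That count was 19 without tail nonLRC replicate 2, 108 without tail LRC replicate 2, 123 without tail nonLRC replicate 1, 175 without tail LRC replicate 1 and 525 without tail midLRC replicate 2, and 1541, 1592, 1395 and 1369 without back LRC replicate 1, back LRC replicate 2, back nonLRC replicate 1 and back nonLRC replicate 2. It was 95 with the stricter cell filter, 223 at a mitochondrial limit of 10%, 262 from basal-like clusters alone, 362 without low quality clusters, 462 by DESeq2, 475 with equal cells, 1564 with no filter on low counts and 1784 from the 6 tail libraries alone.

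**Figure D2:**
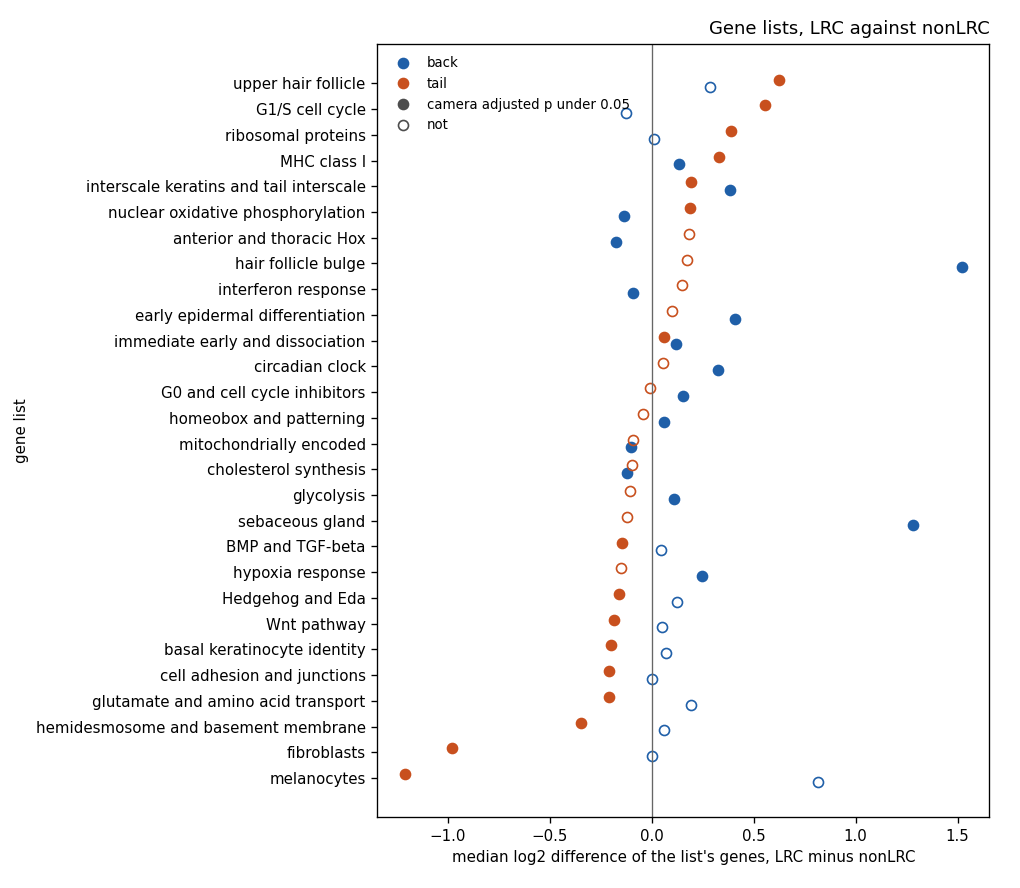
Median log2 difference between LRC and nonLRC of 28 gene lists in back and in tail, one mark per list and skin, from the fit without the block, with filled marks for lists with a camera adjusted p under 0.05 with the replicate block. Bulge genes stand at 1.52 in back, ribosomal protein genes at 0.39 in tail, and hemidesmosome and basement membrane genes at -0.35 in tail.

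Taking both skins together asked what label retention had in common in the 4 LRC and 4 nonLRC libraries. Krt15, a keratin of basal and bulge cells, was higher in LRC by 0.65 ± 0.07 (SE, edgeR with the block, adjusted p = 0.000447), and Krt10 by 0.37 (adjusted p = 0.0126), while Krt14 fell by 0.41 (adjusted p = 0.00674). Tmem176a fell by 1.57, Tmem176b by 1.32, Timp3 by 0.85, Amotl2 by 0.77 and Efemp1, a fibulin gene, by 0.63. Tmem176b and Timp3 were called in back but not in tail (edgeR adjusted p = 0.131 and 0.186), and Tmem176b differed between the skins by 1.41. Krt10 was called in back but not in tail (adjusted p = 0.119). Slc35e4, Tnip2, Fam174a and Rps3a1 rose by 0.28 to 0.49, and these 4 were the only rising genes that met every condition for naming. None of them was called in both skins. Ribosomal protein genes rose in 8 of 78, and 31 adjusted over the list alone (camera with the block, adjusted p = 3.74e-21, and adjusted p = 0.571 with an estimated correlation). In back alone none of them was called and the list did not pass (camera with the block, adjusted p = 0.946). Early differentiation genes rose in 4 of 19, 6 adjusted over the list alone (camera with the block, adjusted p = 5e-05, and adjusted p = 0.571 with an estimated correlation), while in tail alone that list did not pass (adjusted p = 0.0953). Immediate early and dissociation genes rose in 4 of 27, Hspa1a, Dnajb1, Dusp1 and Ier3, each in 4 of 4 pairs, and 5 adjusted over the list alone (camera with the block, adjusted p = 7.95e-05, and adjusted p = 0.571 with an estimated correlation).

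Across the 13583 genes the log2 differences in back and tail, which share no library, had a Pearson correlation of -0.00941 and a Spearman correlation of 0.019, as a description across genes that are not independent replicates. With the block 81 genes were called in both skins, 53 in the same direction and 28 in opposite directions. The 23 that rose in both, where independent lists would share 5.75, included Krt15, Krt6a, Calm4, Il1r2, Bnip3 and Dbp, and the 30 that fell in both, against 7.5, included Krt14, Tmem176a, Casp1, Sparc and Amotl2. Genes that rose in back and fell in tail numbered 20, against 8.25 for independent lists. Those that fell in back and rose in tail numbered 8, against 5.22. For the mean of both skins edgeR called 0 genes with 6 group means, with 575 at an unadjusted p under 0.05 and 57 by DESeq2, and 489 with the replicate block, 220 up and 269 down. The blocked count was 64 without tail nonLRC replicate 2, 158 without tail LRC replicate 2, 181 without tail nonLRC replicate 1, 256 without tail LRC replicate 1, 771 without back nonLRC replicate 1 and 956 without back LRC replicate 1. It was 21 in a model of the 8 LRC and nonLRC libraries alone, 190 with the stricter cell filter, 260 with equal cells and 1170 with no filter on low counts.

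The test of whether the LRC difference itself differed between tail and back gave the following genes. Gpnmb, at log2 -3.54 ± 0.32 (SE, edgeR with the block, adjusted p = 0.000256), Limch1 (-3.43), the Wnt ligand gene Wnt5a (-2.38), Hoxc13 (-2.25) and Cttnbp2 (-2.13) were lower in LRC in tail relative to back, although within basal-like clusters alone Hoxc13 turned to 0.831 and Limch1 did not pass. Prkaa2, a catalytic subunit gene of AMP-activated kinase, was higher by 2.24, H2afy2 by 2.21, Lgals9 by 2.15, Stfa3 by 1.93 and Art3 by 1.62. For these genes the limit of 10 CPM was a mean over both skins, which a high level in either skin can meet. Limch1 and Wnt5a were far lower in tail than in back, and Hoxc13 was lower in back than in tail. Their differences may thus rest partly on low levels in the skin that had less. Ribosomal protein genes had a median difference of 0.39 (camera with the block, adjusted p = 5.89e-21) and nuclear oxidative phosphorylation genes of 0.34 (adjusted p = 1.16e-17), and hemidesmosome genes of -0.33 (adjusted p = 6.49e-08). With an estimated correlation these gave adjusted p = 0.301, adjusted p = 0.289 and adjusted p = 0.211. edgeR called 0 genes with 6 group means, with 553 at an unadjusted p under 0.05 and 25 by DESeq2, and 477 with the replicate block, 193 higher and 284 lower. That count was 10, 100, 118, 167, 277 and 285 without tail nonLRC replicate 2, tail LRC replicate 2, tail nonLRC replicate 1, tail LRC replicate 1, tail midLRC replicate 2 and tail midLRC replicate 1, and 869 and 956 without back LRC replicate 2 and back nonLRC replicate 1. It was 89 with the stricter cell filter, 225 at a mitochondrial limit of 10%, 281 without low quality clusters, 285 with equal cells and 1248 with no filter on low counts.

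The intermediate fraction was compared with both ends. In back, Calml3 was higher in LRC than in midLRC by 2.30 ± 0.21 (SE, edgeR with the block, adjusted p = 0.00171) and Pyy by 0.57 (adjusted p = 0.00268), and Tmem176a was lower by 1.41 (adjusted p = 0.00149). Calml3 was among the leading genes of the bulge-like cluster. Bulge-like cells were 1.60% ± 0.786 of back LRC and 0.160% ± 0.0507 of back midLRC (SD, n = 2). Pyy averaged 184 CPM in back midLRC and Tmem176a 13.4 CPM, between the other fractions, and Foxp2 averaged 6.41 CPM in tail midLRC, whereas Calml3 averaged 4.32 CPM in back midLRC, below nonLRC. Of the genes called between LRC and nonLRC with the block, 87.0% in back and 80.7% in tail had their midLRC mean between the other means, which the choice of these genes partly builds in. edgeR with 6 group means called 0 genes in each of these 4 comparisons, with 298 and 453 at an unadjusted p under 0.05 for LRC against midLRC in back and tail and 157 and 177 for midLRC against nonLRC, where DESeq2 called 13, 45, 2 and 5. With the replicate block the counts were 117, 415, 18 and 16.

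Tail and back skin differed in many genes. All tail libraries came from day 51 and all back libraries from day 47, so skin and age at harvest varied together. The p-values of this comparison, for genes and lists, take the 6 libraries of a skin as independent. Same-numbered libraries of a skin deviated together, so small changes in particular are less certain than these p-values say. Posterior Hox genes, which pattern the caudal body, were higher in tail in 11 of 11 measured members, 11 adjusted over the list alone (camera adjusted p = 5.42e-08, and adjusted p = 0.0123 with an estimated correlation). Hoxd11, on chromosome 2 (74679557 to 74687016, GRCm38), averaged 157 ± 12.5 CPM in tail (SD, n = 6) and 0 in every back library, at least 1353-fold higher against a floor of 3 counts per library, and Hoxd10 was at least 206-fold higher. Hoxd9 had 6031 counts in tail and 3 in back, a ratio of 2408 with a counting interval of 824 to 11680. Anterior and thoracic Hox genes were lower in 16 of 17, among them Hoxa5 at -3.89 and Hoxc4 at -5.47, while Hoxd8 rose by 10.55 (camera adjusted p = 3.78e-07, and adjusted p = 0.321 with an estimated correlation). Hoxd8 overlaps Hoxd3os1, which rose by 10.85, on the opposite strand. Dlx1 rose by 4.08 (edgeR adjusted p = 9.57e-07), from 0.356 to 5.66 CPM, and Slc1a3, a glutamate transporter gene, fell by 0.64 (adjusted p = 0.0076).

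Keratins also separated the skins. Krt77 stood at 770 ± 201 CPM in back and 0.671 ± 0.131 in tail (SD, n = 6), a log2 difference of -10.07 ± 0.23 (SE, edgeR adjusted p = 1.2e-08), and Krt15 fell by 1.54, whereas Krt2 rose by 5.46, Krt1 by 1.28 and Krt14 by 0.38. Of 7 tail scale keratins 4 rose, 6 adjusted over the list alone, including Krt36 at 11.23, though camera gave an adjusted p of 0.175 for that list, and adjusted p = 0.575 with an estimated correlation. Krt36 ranged from 1.89 to 261 CPM among the tail libraries, and Krt84 had 10810 counts in tail and 3 in back, a ratio of 4315 with a counting interval of 1476 to 20930. Krt31 did not pass (edgeR adjusted p = 0.0677). Late differentiation genes were lower in 13 of 17 with Tgm3 rising by 2.48 (camera adjusted p = 0.0192, and adjusted p = 0.556 with an estimated correlation). Krt5, Krt10, Ly6a, Itga6, Col17a1, Mki67 and Top2a did not pass. The other genes named for the size of their rise were led by Fras1 (8.49), Mettl7a3 (7.88) and the insulin-like growth factor binding protein gene Igfbp2 (7.15). Among those that fell, Cfap57 stood at -9.80, Tnxb at -8.17 and Limch1 at -7.72, and 3 more had 3 counts or fewer in tail. These were Fam71a with a back to tail ratio of 13740 (counting interval 2467 to 542900), Pkib with 4463 (1527 to 21640) and Skint7 with 1347 (461 to 6536).

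Genes of antigen presentation and the interferon response were lower in tail. All 10 measured MHC class I genes fell, 10 adjusted over the list alone, with B2m, the light chain gene of these molecules, at 45.0 CPM in tail and 1650 in back and H2-K1 at 80.3 and 2343 CPM (camera adjusted p = 1.88e-09, and adjusted p = 0.0108 with an estimated correlation). H2-Q7 fell by 9.21, H2-Q6 by 7.53 and Nlrc5, a transactivator gene of this class, by 8.17, and the H2-Q genes are near-identical copies whose reads can be shared. Interferon response genes fell in 21 of 22, 21 adjusted over the list alone, led by Psmb9 (-4.65), Psmb8 (-5.80) and Usp18 (-7.04) (camera adjusted p = 1.47e-11, and adjusted p = 0.00868 with an estimated correlation). Langerhans and myeloid cell genes fell in 7 of 9 and Mfge8 rose, with H2-Eb1 at 1.04 CPM in tail and 7.65 in back (camera adjusted p = 0.0107, and adjusted p = 0.548 with an estimated correlation). Immediate early and dissociation genes were lower in 21 of 27, at a median of -3.59 (camera adjusted p = 7.99e-09, and adjusted p = 0.548 with an estimated correlation), with Jun at 85.0 CPM in tail and 3900 in back and Fos at 37.2 and 3967 CPM. The median level of the list was 1330 CPM in back replicate 1 and 344 in back replicate 2, and 56.7 and 45.4 CPM in tail. Cluster 0, with Fos and Jun among its leading genes, held 1755 of 4763 cells in back nonLRC replicate 1 and 8 of 2223 in replicate 2. G1/S genes rose in 22 of 28, with Gins2 at 1.52 and Mcm4 at 1.39 (camera adjusted p = 1.37e-06, and adjusted p = 0.575 with an estimated correlation), while of 30 G2/M genes only Ttk changed, falling by 1.24. Circadian clock genes rose in 11 of 17 and fell in 2, with Bhlhe41 at 5.33 and Arntl at -1.73 (camera adjusted p = 0.0107, and adjusted p = 0.193 with an estimated correlation). In all, edgeR called 7027 of 13583 genes, 3471 higher and 3556 lower in tail. Same-numbered libraries of a skin deviated together, so the 6 libraries of a skin hold 2 sets and are not independent. With sums over the 3 fractions of each set, 2 against 2, edgeR called 2674 of 14322 genes, 1185 higher and 1489 lower.

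**Figure D3:**
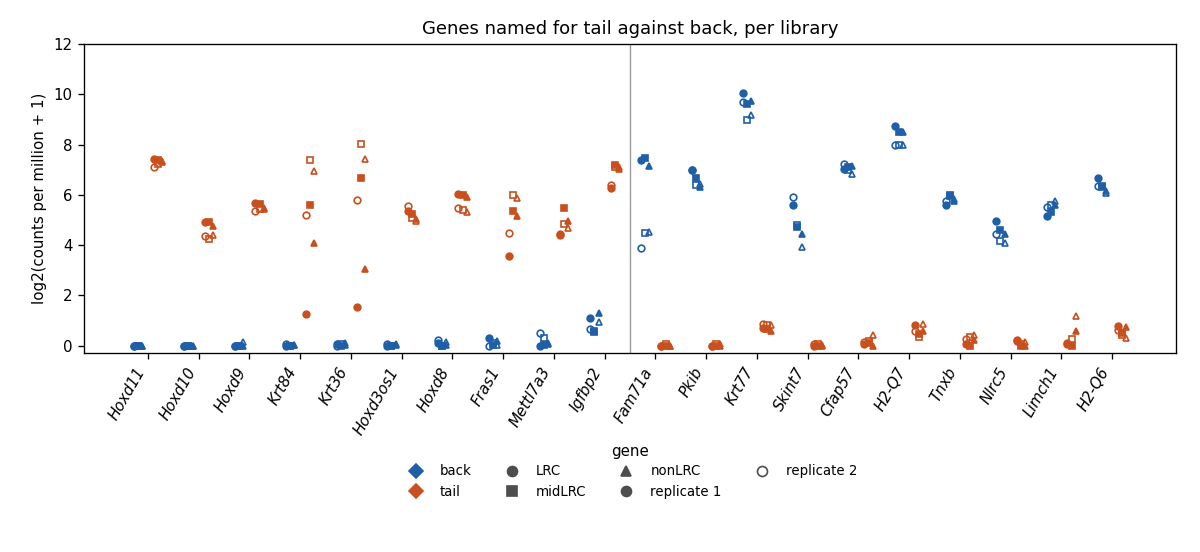
Level of the 20 genes named for the size of their tail against back difference, as log2 of CPM + 1 in each of the 12 libraries, with skins in separate colours, fractions as marker shapes and replicate 1 filled. Hoxd11 is at 0 in every back library and averages 157 CPM in tail, and Krt77 averages 770 CPM in back and 0.671 in tail.

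The share of cycling cells, those with 3 or more UMIs of G2/M genes after thinning each cell to 3000 UMIs, differed between LRC and nonLRC within skins by -5.46 percentage points, which did not pass (two-sided exact permutation p = 0.111, where the smallest possible is 0.0556). In back it was 11.6% ± 6.33 in LRC, 13.8% ± 4.24 in midLRC and 17.5% ± 3.05 in nonLRC, and in tail 22.4% ± 2.87 in LRC and 27.4% ± 1.79 in nonLRC (SD, n = 2), with midLRC between them. Without thinning these shares were 27.6%, 35.5% and 35.8% in back and 44.4%, 40.7% and 42.6% in tail, where the order of LRC and nonLRC turned. Thinning left out 98, 77 and 237 cells in the back fractions and 416, 2588 and 1537 in the tail fractions. The thinned share was lower in LRC than in nonLRC in each of the 4 replicate pairs, which the test did not use. The share of cells in cycling-like clusters was also lower in each pair, at 10.5% ± 4.79 in LRC and 17.2% ± 0.852 in nonLRC in back and 13.9% ± 1.82 and 17.6% ± 3.18 in tail (SD, n = 2). The summed counts of G2/M genes had a median log2 difference of 0.23 in back and 0.16 in tail, opposite to the shares, and no order was read from either. Cells in non-keratinocyte clusters were 0.242% ± 0.0993 in back LRC and 0.396% ± 0.204 in back nonLRC, and 0.0933% ± 0.0610 and 0.493% ± 0.478 in tail (SD, n = 2), a mean difference of -0.276 percentage points (two-sided exact permutation p = 0.167).

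**Figure D4:**
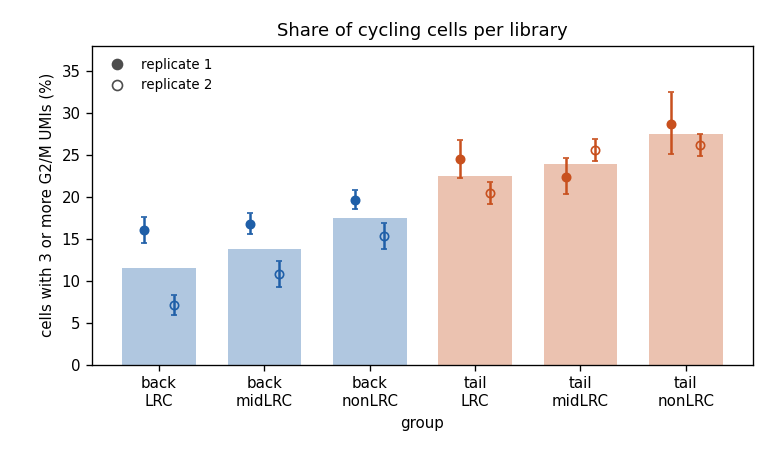
Percent of cells with 3 or more UMIs of G2/M genes after thinning to 3000 UMIs, one point per library with its 95% binomial interval, which covers counting error only, and bars at the group means, for the 3 fractions in back and in tail. Group means run from 11.6% in back LRC to 27.4% in tail nonLRC, and libraries of neighbouring fractions overlap in back.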

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

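The patterns weighed here were picked after the data had been examined and the bounds of their tests were set before the tests were run, while the cell sets without hair follicle-like or low quality clusters and every fit of 1 cell set or without 1 library with the block were chosen after seeing the data.

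The test of the difference between skins, with the replicate block, called 477 genes whose LRC against nonLRC change differed between tail and back, and 31 of the 48 genes named for back, tail or the difference passed it, together with 16 gene lists. The last 10 genes were named for their size in this same test, and those named for 1 skin were chosen for large changes there, so the count of 31 is partly built in. Each value is the log2 difference in tail minus that in back. Of the genes named for back, Calml3 stood at -1.78, Col4a1 at -2.05, Pyy at -0.72, Guca2a at -1.08, H2-M2 at -1.69 and Nat8l at -1.51, all of which rose in back LRC. Of those that fell there, Tmem176a stood at 1.10, Tmem176b at 1.41, Capn2 at 1.19, Lgals9 at 2.15, Dlc1 at 1.38 and Ptn at 1.41. Of the genes that rose in tail LRC, Spats2l stood at 1.54, Pappa at 2.00, Gstm5 at 0.99, Skint1 at 0.65, Etv4 at 2.33 and Krt80 at 0.74, and of those that fell there, Gpnmb at -3.54, Nav1 at -1.72, Sox4 at -1.40, Slc39a10 at -0.85 and Igfbp7 at -1.59. Of the 10 named for the difference, Lgals9 and Gpnmb are given above and the others were Prkaa2 (2.24), H2afy2 (2.21), Stfa3 (1.93), Art3 (1.62), Limch1 (-3.43), Wnt5a (-2.38), Hoxc13 (-2.25, and 0.831 within basal-like clusters alone) and Cttnbp2 (-2.13). Limch1 and Wnt5a were far lower in tail than in back and Hoxc13 lower in back, so these values may rest partly on low levels.

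The lists that passed the test of the difference with camera and the block had the following medians of the log2 difference in tail minus that in back, from the fit without the block. These medians compare the changes from nonLRC to LRC, not the levels of the skins. The change was higher in tail for ribosomal protein genes (0.39), nuclear oxidative phosphorylation genes (0.34), G1/S genes (0.66) and anterior and thoracic Hox genes (0.50). The levels of most of these Hox genes were lower in tail. The change was lower in tail for bulge genes (-1.44), sebaceous gland genes (-1.59), melanocyte genes (-1.91), hypoxia response genes (-0.37), circadian clock genes (-0.34), hemidesmosome and basement membrane genes (-0.33), Wnt pathway genes (-0.32), amino acid transport genes (-0.29), basal keratinocyte genes (-0.22), cell adhesion genes (-0.22), glycolysis genes (-0.21) and homeobox genes (-0.19). None of these lists passed with an estimated correlation, where adjusted p ran from 0.211 to 0.343. Without hair follicle-like clusters the bulge list did not pass (camera with the block, adjusted p = 0.829, and adjusted p = 0.893 with an estimated correlation), and its test pointed up while the median of 8 members with the block was -0.42. Bulge-like cells were 1.60% of back LRC and 0.151% of back nonLRC, and in the opposite order 0.144% ± 0.0101 of tail LRC and 0.929% ± 0.530 of tail nonLRC (SD, n = 2), a difference between skins that was not tested.

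The higher level of bulge genes in back LRC may come from a small number of hair follicle cells in the sort, although a gate on α6 integrin and Sca1 is of the kind used to leave bulge cells out. With all keratinocyte clusters and the block the median log2 difference of the 9 genes was 1.54. Without the hair follicle-like clusters it fell to 0.701, narrowly less than the share of its value set in advance as the bound. With low count genes filtered anew it was 0.825 over 8 members, which kept more than that share. These sums also still held cluster 23, led by the follicle markers Krt17 and Krt24, and Krt24 had 976 counts in them. The side of the bound depends on the filter, so the test of the median cannot decide and that explanation stays open for the list. Single members differed. Without the hair follicle-like clusters Cd34 went from 4.63 to 0.495 with 4 counts left, so its rise lay mainly in those clusters. Lgr5 went from 4.25 to 1.90 with 4 counts left and Tbx1 from 3.05 to 1.63 with 26. Krt24 kept its rise, at 1.54 and 1.59. Within the basal-like clusters alone the median was 0.287, between the bounds set for and against free RNA or scattered follicle cells, over members that went both ways, with Sox9 at -2.35 (1395 counts), Postn at -1.91 (2692 counts), Nfatc1 at 0.29 (1176 counts) and Cd34 and Lgr5 at 2 counts each. The basal-like cells also lay in different clusters, since cluster 9, with Sostdc1 and Sox9 among its leading genes, held 18 of 1919 cells in LRC replicate 2 and 512 of 2223 in nonLRC replicate 2, so that this explanation cannot be told apart from the others. A property of label-retaining interfollicular cells stays open as well and was not tested separately.

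For the 465 genes that fell in tail LRC with the block, leaving out 4 clusters of low UMI counts or extreme mitochondrial share left 100% of them with at least 0.5 of their log2 difference (median -0.528 against -0.585). At least that part of the falls thus did not come from the barcodes of those clusters, although the number of genes called in tail fell from 789 to 361. The same share was 100% without tail nonLRC replicate 1, the library with the fewest cells, a value partly built in by the choice of genes, although the number of genes called then fell to 114 (123 with low count genes filtered anew). A correction for exon length left 99.1%, although the falling genes were longer, with a median exon length of 6514 against 4186 bases for tested genes. The value after the length correction argues against gene length alone as the whole source. The value without those clusters covers only their barcodes and was partly built in, since the genes were called with them. Leaving them out took the sum from 31289579 to 27041113 UMIs in tail nonLRC replicate 2 and from 5468939 to 5314039 in replicate 1. Low quality among the other cells stays open. With the block, the stricter cell filter called 95 genes in tail and a mitochondrial limit of 10% called 223. The direction was kept in 781 of 781 and 785 of 785 genes tested there. The value without tail nonLRC replicate 1 cannot decide about that library, since the genes were chosen from calls that used it. A difference between the LRC and nonLRC fractions is a hypothesis that may account for the pattern. Without tail nonLRC replicate 2 the median was -0.582 and 96.3% kept at least 0.5 of their difference, again partly built in, while only 17 genes were called (19 with low count genes filtered anew), so the calls rest on few libraries.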

How the results depend on the processing

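The settings that combine another choice with the replicate block, the cell sets without low quality or hair follicle-like clusters, and the other mitochondrial limits were chosen after seeing the data. The block alone was among the alternatives set before. The replicate number was taken as a pairing only when the clusters were seen to split by replicate, before any fit. Same-numbered libraries of a skin deviated together, and the replicate block raised the counts of changed genes from 0 to 460 (back), 789 (tail), 489 (mean of both) and 477 (difference between skins), and to 117, 415, 18 and 16 for LRC against midLRC in back and tail and midLRC against nonLRC in back and tail. It moved no other count of genes beyond 1.5 times. In the same order of 8 comparisons, without the block DESeq2 called 56, 32, 57, 25, 13, 45, 2 and 5 genes and no filter on low counts gave 29, 14, 28, 12, 4, 25, 2 and 3, and single settings gave 4 (basal-like clusters alone, back), 1 (no mitochondrial limit, tail) and 1 (equal cells, LRC against midLRC in tail). With the block, back gave 294 by DESeq2, 1019 with no filter on low counts, 246 with the stricter cell filter, 276 with equal cells and 58 from the 6 back libraries alone. Tail gave 462 by DESeq2, 1564 with no filter, 262 from basal-like clusters alone (clusters with leading follicle markers included), 95 with the stricter filter, 475 with equal cells, 362 without low quality clusters, 223 at the limit of 10% and 1784 from the 6 tail libraries alone. The mean gave 1170, 190 and 260 with no filter, the stricter filter and equal cells, and the difference 1248, 89, 285, 281 and 225 with no filter, the stricter filter, equal cells, without low quality clusters and at 10%. The causes were not tested. Leaving out 1 library with no block gave 0 to 2 genes in back, 0 to 1 for the difference and for LRC against midLRC in back, and 0 to 0 for the other 5 comparisons. With the block the ranges were 288 to 763, 19 to 1592, 64 to 956 and 10 to 956. A lone library of a group was assumed to vary like the others. Depth was lowest in tail nonLRC replicate 1, with 716 cells in the sum. In simulated counts, which held a planted replicate difference, 24.2% of back genes changed by log2 1 were recovered without the block and 71.7% with it. For tail against back, sums over the 3 fractions of each skin and replicate number, 2 against 2 with fewer degrees of freedom and chosen after seeing the data, gave 2674 genes, 2567 of them shared with the 7027. No other setting moved that count beyond 1.5 times, with 5928 to 6924 on leaving out 1 library, 7478 with a replicate block common to both skins, where Krt31 passed (edgeR adjusted p = 0.0495), and 7119 by DESeq2.

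Gene lists passing the test numbered 11, 9, 5, 14 and 14 for back, tail, mean, difference and tail against back. With an estimated correlation these were 0, 0, 0, 0 and 3, with or without the block, and with the block without low quality or hair follicle-like clusters. The block gave 17, 16 and 10 for back, tail and mean. With the block, tail and mean gave 15 and 11 without cycling-like clusters, back, tail and mean gave 17, 14 and 11 without low quality clusters, and tail and mean gave 15 and 13 without hair follicle-like clusters. The correlation of the changes in both skins was -0.00941, and -0.0419 without cycling-like clusters, -0.00919 with RLE and -0.00592 with the block. Within replicate numbers it was 0.045 and -0.0217. The cycling share difference lay between -7.70 and -3.22 points and that of non-keratinocyte cells between -0.446 and -0.107 on leaving out 1 library. Named genes with other settings kept direction and call in 2005 values and lost the call in 266. In 1 value the direction turned, Hoxc13 in the difference between skins (basal-like clusters alone with the block, 0.831). Lists kept both in 257 values and lost the call in 218. The test of bulge genes in the difference turned without hair follicle-like clusters with the block (camera adjusted p = 0.829, and adjusted p = 0.893 with an estimated correlation). Bulge-like cells were more frequent in LRC in back and in nonLRC in tail, and whether that is the cause was not tested.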

Other observations

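The gene groups were fixed before the data were examined, the genes named singly here were chosen after their values were seen, and the estimated correlation together with the block and the pattern weighed were chosen after seeing the data.

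Further gene groups moved within the fractions. In back LRC, genes of glycolysis rose in 2 of 15, Slc16a3 by 0.72 and Pfkfb3 by 0.90 (camera with the block, adjusted p = 0.00623, and adjusted p = 0.46 with an estimated correlation), and Glul, which encodes glutamine synthetase, rose by 0.41, while cholesterol synthesis genes were lower as a group at a median of -0.12 (camera with the block, adjusted p = 0.00461, and adjusted p = 0.323 with an estimated correlation). The cell cycle inhibitor genes Cdkn1a and Cdkn2b rose by 0.43 and 0.63. In tail LRC the Notch genes Jag2, Dll1 and Notch1 fell by 0.41, 0.53 and 0.34, although the Notch list of 16 did not pass, and Smo, the Hedgehog signal transducer gene, fell by 0.46 in a list that passed (camera with the block, adjusted p = 0.0234, and adjusted p = 0.385 with an estimated correlation). The homeobox gene Dlx3 fell by 1.82 and Igfbp2 by 0.73. Upper hair follicle genes had a median of 0.62 and a test that pointed up (camera with the block, adjusted p = 0.0253, and adjusted p = 0.385 with an estimated correlation), but the members called, Klk10 and Lgr6, fell. Upper hair follicle-like cells were 4.02% of tail LRC and 4.71% of tail nonLRC in replicate 1, and 6.48% and 2.47% in replicate 2.

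Between skins, glycolysis genes were lower in tail in 11 of 15, with Slc16a3, a lactate transporter gene, at 6.20 CPM in tail and 52.2 in back (camera adjusted p = 0.000748, and adjusted p = 0.548 with an estimated correlation). The water channel gene Aqp3 averaged 1041 CPM in tail and 82.2 in back, and Mgst1 93.4 and 16.7 CPM. Unfolded protein response genes fell in 11 of 20 and rose in 2 (camera adjusted p = 0.0107, and adjusted p = 0.548 with an estimated correlation), and p53 target genes fell in 9 of 21 and rose in 1, with Plk2 at 6.08 and 75.2 CPM (camera adjusted p = 0.0416, and adjusted p = 0.556 with an estimated correlation). Wnt5a fell by 5.73 while the cyclin gene Ccnd1 rose by 1.28.

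The immediate early genes, higher in back, are often raised by the handling of tissue, so the difference may come from 1 back replicate. In replicate 2 alone the median log2 difference of the 27 genes, tail minus back, was -2.755, far beyond the bound of -0.3 set in advance, and in replicate 1 it was -4.242, which argues against the handling of 1 replicate as the whole source. Handling that differed between all back and all tail libraries, age and skin site remain open and untested.

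Other splits of the libraries were counted for the results that compare at least 3 libraries per group. For the mean of both skins without the block the real split gave 0 genes, so each of the 35 splits gave at least as many by construction and the count says nothing of chance. The highest, 5740, was the split by skin, followed by 533 for a split that crossed the replicate numbers between skins and 30 for the split by replicate number, which points to skin and replicate as structures of these libraries larger than the fractions. With the block, among 8 splits that part the 4 pairs, the real one gave 21 genes in the model of 8 libraries and the highest other 4, and 8 splits are too few for a share under 0.05. For tail against back, 1 of the 60 splits drawn from 462 gave as many genes as the real 7570 in an additive model of fraction and split, namely the real one, and the highest other gave 0. Those splits take the 12 libraries as exchangeable, whereas same-numbered libraries of a skin deviated together, and splits that keep such sets whole are too few for a share under 0.05.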
